A study of Homo sapiens with 12 samples.

How the data were processed

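The RNA of 12 cultures or wells of Caco-2, a human colon adenocarcinoma line that forms an enterocyte-like monolayer, was sequenced in 4 groups of 3 replicates. Per the labels' protocols, the cells were grown for 21 days on transwell inserts and then given buffer alone (control), Bacillus subtilis CW14 (CW14), ochratoxin A at 15 µmol/L in the apical chamber (OTA), or both (OTA plus CW14, called the combined group). The labels do not give the time of exposure. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

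Per the labels' protocols, libraries were made with an RNA kit that does not mark strand as far as the labels say, and were read as 150-base pairs. The deposited values are FPKM per gene and library, fragment counts scaled to transcript length and to the library's mapped fragments, which the authors made. Per the submitters' processing notes, the tools were cutadapt 1.10, TopHat2 2.0.13, Cufflinks 2.2.1, Cuffnorm and Cuffdiff, and the build was hg19; the notes give no role or order, and the annotation and the scaling between libraries are not given in the sources used here. The table held 26125 genes or transcripts by symbol, with a locus each and 1 column per library. Loci are printed as deposited, in hg19; whether starts are counted from 0 or 1 is not stated, and a locus of this kind can span neighbouring genes.

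FPKM are not counts, and absolute depth was not given. Low FPKM values of a gene step in whole fragments, so the most common ratio of low values (under 0.3 FPKM in both libraries, tolerance 0.01 on the log2 scale) against control replicate 1 was used to recover relative depth, a check added after the data were seen. It gave 1, 1.58 and 0.908 for the controls, 0.892, 0.776 and 0.856 for CW14, 1.61, 0.657 and 1.16 for OTA and 0.642, 0.669 and 0.471 for the combined group. These ratios include any scaling between libraries. The lowest was that of combined replicate 3. Small RNA genes (2273 in the table, 75 of them tested) held 81.8% to 97.4% of the FPKM sum of a library, up to 15800000 FPKM for 1 gene, so column sums were not used as a measure of depth. In 28 entries a date stood in place of a gene symbol, and 19 of these were tested without being named. An exact 0 can be a failed estimate: 21 genes with a median over 5 FPKM had a 0 in some library, and 13 of those zeros lay in combined replicate 3. Genes at 0 are therefore described as listed at 0, with each library's value.

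Values were analysed as log2(FPKM + 1) for the 12928 genes with a mean of at least 1 FPKM over the 12 libraries. A log2 difference on this scale understates the change of low genes. A linear model with a mean per group was fitted to all 12 libraries in limma 3.58.1 (R 4.3.3), with an empirical Bayes step with an intensity trend, 8 residual degrees of freedom and two-sided tests. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were OTA against control, CW14 against control, the combined group against OTA, against control and against CW14, the interaction of OTA and CW14, and any difference among the 4 groups (F test). A gene was counted as reversed when it was called in OTA against control and called in the opposite direction in the combined group against OTA.

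Gene lists were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with the rotation test fry, which tests whether a list's genes move, on balance, in a common direction. The lists were tight junction, adherens junction and desmosome, actin cytoskeleton, brush border, lipid absorption and lipoproteins, fatty acid oxidation, nutrient and ion transporters, enterocyte transcription factors, xenobiotic metabolism and efflux, NRF2 targets, ATF4 and integrated stress response, aminoacyl-tRNA synthetases, unfolded protein response, heat shock proteins, metallothioneins, p53 targets, apoptosis, NF-kB and inflammatory cytokines, interferon response, bacterial sensing and antimicrobial, immediate early and MAPK, hypoxia targets, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded, ribosomal proteins, mitosis, DNA replication, cholesterol synthesis and uptake, histones with polyadenylated transcripts, mesenchymal transition and TGF-beta, mucins and goblet cell, crypt stem cell and Wnt, enteroendocrine, autophagy and lysosome and other cell types, stromal immune and endothelial. A list needed 5 tested members, which left 34: no mitochondrially encoded gene was in the table, and 2 of 11 enteroendocrine genes passed the filter. The text names genes by a rule fixed beforehand: the 10 largest rises and falls among called, non-overlapping genes in the first 3 comparisons (5 in the others), up to 4 called members of each list that passed, and a fixed set of junction genes, among them CLDN1, CLDN2, CLDN3, CLDN4, OCLN, TJP1, F11R, CDH1 and MYLK, in every comparison. Small RNA and locus-number names were left out of the ranks, and not every gene the rule takes is printed.

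GC content, transcript length and the density of the ATTTA motif in 3' untranslated regions came from the longest coding transcript of the same symbol in GENCODE release 29; 12148 of the 12928 tested genes (94.0%) matched, and no coordinate was taken from it. Alternatives covered the pseudocount (0.1 and 5), the filter (none, or a mean of 5 FPKM), scaling (median-centring, quantile normalization, upper quartile), a fit with only the compared groups, array weights (gene-by-gene method, since the default did not converge), no intensity trend, a replicate block, and leaving out each library in turn. Those added after the data were seen were a fit without small RNA genes, removal of each library's smooth trend on GC content and length, and the leave-one-out runs of the list tests. Simulated data for OTA against control (12928 genes) tested the model. At log2 differences of 0.5, 1, 2 and 4, the calls in the right direction were 3, 31, 48 and 50 of 50 changed genes. Of 12698 unchanged, 6 were called. There CW14 against control had 0 calls. A simulated list passed and 0 of 34 real ones did, against up to 17 in other splits of real libraries. Figures were drawn with matplotlib 3.10.9.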

Results

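Gene expression was measured by RNA sequencing in 12 libraries of Caco-2 cells, 3 from each of 4 groups. The groups were control, Bacillus subtilis CW14 alone, ochratoxin A (OTA) alone at 15 µmol/L, and both together (the combined group). OTA is a mould toxin that contaminates food, and the series title presents CW14 as a probiotic and asks about barrier disruption and toxicity of OTA. Values are FPKM on the deposited scale, and ± is the SD of 3 libraries (n = 3) throughout.

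The libraries separated mainly by OTA. Principal component 1 held 35.3% of the variance, with control and CW14 libraries at scores of 26.7 to 36.6 and all libraries with OTA below 0. Combined replicate 3 stood apart, at -83.3 on component 1 and 51.7 on component 2. Its residual SD was 0.588, against 0.305 to 0.424 in the other libraries. Its mean correlation with its group was 0.885. Its deviation from the mean of all libraries followed transcript GC content (rho = 0.508) more closely than that of any other library, and its recovered depth ratio was the lowest.

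**Figure D1:**
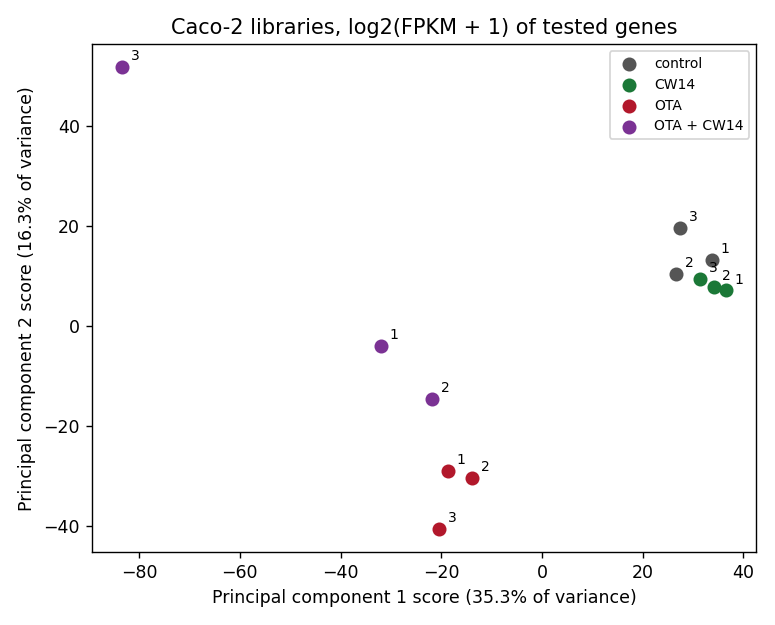
Scores of the 12 libraries on the first principal components of log2(FPKM + 1), with replicate numbers beside the points and colours for the groups. Component 1 holds 35.3% of the variance and component 2 16.3%. Combined replicate 3 lies at -83.3 and 51.7, away from the other combined libraries.

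Of 12928 genes tested, 4845 differed among the 4 groups (limma, adjusted p under 0.05). OTA differed from control in 2288 genes and CW14 in 47. The combined group differed in 2070 from OTA, 3729 from control and 4179 from CW14. With only the compared groups fitted, 2288 became 4621 and 2070 became 70. The median standard error of a log2 difference was 0.212.

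**Figure D2:**
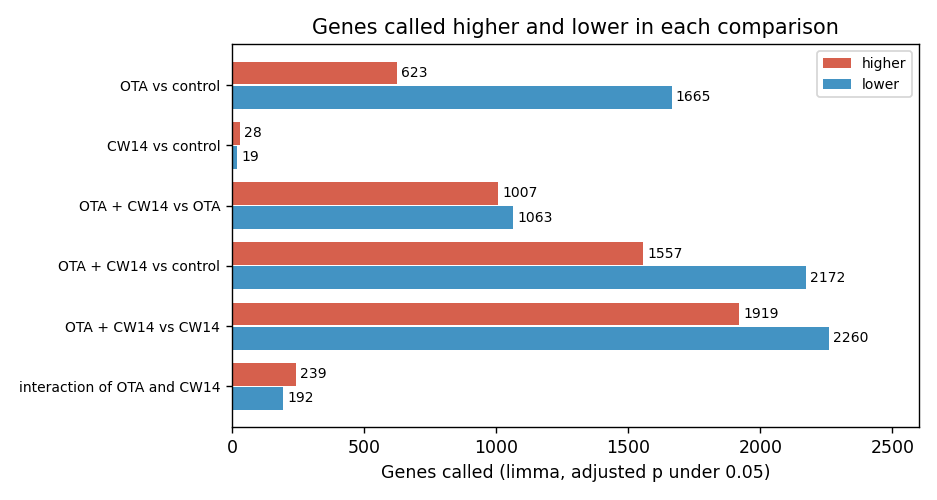
Number of genes called higher and lower (horizontal bars, limma, adjusted p under 0.05) in each comparison. CW14 alone gave 28 higher and 19 lower genes, against 623 and 1665 for OTA alone.

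OTA against control asks what the toxin alone did. The genes that fell most include those that cells switch on within minutes of a growth or stress signal. EGR1, an immediate early transcription factor (chromosome 5, 137801179 to 137805004), fell from 270.2 ± 18.4 to 21.9 ± 4.85 FPKM (log2 difference -3.58, SE 0.16, limma adjusted p = 4.6e-07). DUSP1, a phosphatase that switches off MAP kinases, fell from 272 ± 6.86 to 25.7 ± 2.26 FPKM. FOSL1 fell from 67.6 ± 7.75 to 6.79 ± 0.731, and DUSP5 from 225 ± 11.9 to 25.5 ± 6.40. Of the 34 immediate early and MAPK genes, 0 rose, 33 fell and 1 did neither (0 and 34 adjusted over the list alone). Their median log2 difference was -2.21. For immediate early and MAPK genes, camera gave adjusted p = 1.81e-37 (0.00569 with an estimated correlation). TRIB1, a pseudokinase, had the largest fall of the ranked genes, from 173 ± 16.5 to 12.6 ± 3.28 (log2 difference -3.70, SE 0.21, limma adjusted p = 8.72e-07). PCK1, a key enzyme of gluconeogenesis, fell from 131 ± 41.9 to 9.55 ± 2.29 FPKM. SERTAD1, CSRNP1 and C11orf96 fell by 3.18, 3.17 and 3.51 on the log2 scale. RAD51L3-RFFL, a read-through name whose fragments cannot be told from those of its neighbours, had control values of 35.7 ± 10.6 and OTA values of 6.80, 0.00305 and 6.95.

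Some stress and damage genes fell as well. Of the 25 p53 targets, 0 rose, 14 fell and 11 did neither (0 and 15 adjusted over the list alone). For p53 targets, camera gave adjusted p = 7.95e-07 (0.0235 with an estimated correlation). BTG2 fell from 178 ± 38.0 to 21.1 ± 6.56, and PLK2 from 35.7 ± 1.09 to 3.59 ± 0.220. GDF15 fell from 634 ± 48.5 to 95.4 ± 25.8, and BBC3 from 80.1 ± 7.44 to 14.9 ± 3.84. GDF15 encodes a stress cytokine and BBC3 a promoter of cell death. Of the 22 ATF4 and integrated stress response genes, 0 rose, 14 fell and 8 did neither (0 and 14 adjusted over the list alone). For ATF4 and integrated stress response genes, camera gave adjusted p = 2.24e-10 (0.0876 with an estimated correlation). CHAC1, which degrades glutathione, fell from 38.0 ± 4.06 to 2.19 ± 0.7499 FPKM. DDIT4, an inhibitor of mTORC1, fell from 1222 ± 84.7 to 145 ± 35.0 FPKM. ATF3 fell from 198 ± 7.52 to 25.4 ± 5.58, and PPP1R15A from 708 ± 81.4 to 94.3 ± 17.5. Of the 26 NF-kB and inflammatory cytokine genes, 1 rose, 13 fell and 12 did neither (1 and 16 adjusted over the list alone). For NF-kB and inflammatory cytokine genes, camera gave adjusted p = 1.19e-06 (0.437 with an estimated correlation). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, fell from 215 ± 32.1 to 24.6 ± 3.22 FPKM. IER3 fell from 448 ± 66.2 to 56.9 ± 1.31, and CCL20 from 134 ± 54.2 to 17.9 ± 3.16. Of the 24 apoptosis genes, 1 rose, 9 fell and 14 did neither (1 and 11 adjusted over the list alone). For apoptosis genes, camera gave adjusted p = 0.000823 (0.0876 with an estimated correlation). The members that fell act on both sides of cell death. MCL1, which blocks it, fell from 345 ± 53.4 to 54.1 ± 11.4 FPKM. PMAIP1, which promotes it, fell from 32.1 ± 5.52 to 4.41 ± 0.243 FPKM. Of the 16 heat shock proteins, 0 rose, 7 fell and 9 did neither (0 and 9 adjusted over the list alone). For heat shock proteins, camera gave adjusted p = 0.000274 (0.27 with an estimated correlation). DNAJB1 fell from 436 ± 64.0 to 77.5 ± 7.63, and HSPA6 from 84.7 ± 6.75 to 19.3 ± 2.91. HSPA1A and HSPA1B, near-identical copies whose fragments can be split between them, fell by 1.52 and 1.33 on the log2 scale.

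The unfolded protein response, interferon and metallothionein lists had higher camera adjusted p. Of the 22 unfolded protein response genes, 0 rose, 6 fell and 16 did neither (0 and 6 adjusted over the list alone). For unfolded protein response genes, camera gave adjusted p = 0.0431 (0.437 with an estimated correlation). HERPUD1 fell from 275 ± 19.1 to 49.3 ± 8.54, and HSPA5 from 919 ± 56.9 to 405 ± 5.80. The unfolded protein response call was lost without any of control replicate 3, CW14 replicate 3, OTA replicate 1, combined replicate 1 or combined replicate 3 (camera adjusted p up to 0.0787). Of the 21 interferon response genes, 0 rose, 5 fell and 16 did neither (0 and 5 adjusted over the list alone). For interferon response genes, camera gave adjusted p = 0.0321 (0.437 with an estimated correlation). The interferon call was lost without control replicate 3 (camera adjusted p up to 0.0971). IRF1 fell from 15.7 ± 0.742 to 5.03 ± 1.54, and IFIT2 from 10.2 ± 1.11 to 4.34 ± 0.304. Of the 6 metallothionein and zinc genes, 0 rose, 2 fell and 4 did neither (0 and 4 adjusted over the list alone). For metallothionein and zinc genes, camera gave adjusted p = 0.0164 (0.541 with an estimated correlation). The metallothionein call was lost without control replicate 1 (camera adjusted p up to 0.0524). MT1X fell from 121 ± 134 to 12.2 ± 8.41, and SLC30A1 from 135 ± 61.9 to 36.1 ± 5.04.

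Among junction genes, CLDN4, a tight junction claudin (deposited locus chromosome 7, 72476601 to 74336166, which spans neighbouring genes), fell from 1770.1 ± 60.7 to 412 ± 60.7 FPKM with OTA (log2 difference -2.11, SE 0.14, limma adjusted p = 2.35e-06). The scaffold gene TJP1 (chromosome 15, 29991569 to 30261002) fell from 44.3 ± 3.57 to 13.9 ± 0.269 (log2 difference -1.60, SE 0.21, limma adjusted p = 0.000237). OCLN, which encodes occludin (chromosome 5, 68788117 to 68853931), fell from 83.4 ± 5.36 to 41.8 ± 5.24 (log2 difference -0.98, SE 0.14, limma adjusted p = 0.000438). CLDN3 fell from 126 ± 10.7 to 71.9 ± 6.88 FPKM. CLDN1, CLDN2, F11R, CDH1 and MYLK were not called, with log2 differences of 0.38, 0.23, -0.24, 0.21 and -0.23. Of the 28 tight junction genes, 1 rose, 6 fell and 21 did neither (1 and 6 adjusted over the list alone). The list did not pass camera (adjusted p = 0.14) but was lower by fry (adjusted p = 0.00252). Of the 18 enterocyte transcription factors, 0 rose, 8 fell and 10 did neither (1 and 8 adjusted over the list alone). For enterocyte transcription factors, camera gave adjusted p = 0.00104 (0.117 with an estimated correlation). ELF3 fell from 237 ± 21.6 to 49.4 ± 7.95, and FOXA2 from 59.8 ± 1.62 to 18.0 ± 1.82. ISX fell from 13.3 ± 1.55 to 3.55 ± 0.392, and GATA6 from 47.8 ± 8.68 to 15.00 ± 2.03.

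Fewer genes rose with OTA. Of the 10 largest rises, 9 were histone genes of the replication-dependent clusters, whose near-identical copies can share fragments. HIST1H2AL rose from 2.17 ± 0.892 to 19.4 ± 5.02 FPKM (log2 difference 2.70, SE 0.26, limma adjusted p = 2.63e-05). HIST2H3A rose from 4.14 ± 4.22 to 21.2 ± 4.97, and HIST1H2AI from 3.47 ± 1.497 to 22.7 ± 8.17. HIST1H2AM rose from 7.96 ± 2.33 to 44.9 ± 5.96, and HIST2H2BF from 11.9 ± 1.04 to 48.4 ± 12.03. HIST1H2BE had control values of 0.930, 1.80 and 0 and 6.97 ± 1.68 with OTA. HIST1H2AJ had control values of 1.18 ± 0.759 and 6.75 ± 1.20 with OTA. HIST1H2BM had control values of 0, 1.14 and 0 and 3.78 ± 1.42 with OTA. HIST2H2AB had control values of 0, 1.13 and 0 and 3.32 ± 1.01 with OTA. The remaining one was RUSC1-AS1, an antisense gene that cannot be told from its partner strand here, with control values of 0, 1.33 and 1.80 and 5.90 ± 3.58 with OTA.

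Lists of basic metabolism and of ribosomal proteins shifted up by small steps in camera, and none of these 5 passed fry. Of the 55 ribosomal protein genes, 7 rose, 0 fell and 48 did neither (7 and 0 adjusted over the list alone). For ribosomal protein genes, camera gave adjusted p = 5.29e-07 (0.541 with an estimated correlation). RPL3 rose from 460.1 ± 37.8 to 766 ± 25.4, and RPS13 from 257 ± 23.8 to 445 ± 10.98. Of the 46 nuclear-encoded respiratory chain genes, 5 rose, 0 fell and 41 did neither (5 and 0 adjusted over the list alone). For nuclear-encoded respiratory chain genes, camera gave adjusted p = 8.52e-05 (0.562 with an estimated correlation). ATP5C1, an ATP synthase subunit, rose from 35.3 ± 2.78 to 54.9 ± 1.33 FPKM. Of the 18 glycolysis genes, 3 rose, 0 fell and 15 did neither (3 and 0 adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 9.38e-05 (0.499 with an estimated correlation). PGAM1 rose from 163 ± 4.37 to 273 ± 12.6, and LDHA from 1238 ± 94.6 to 1842 ± 67.7. Of the 27 hypoxia targets, 9 rose, 3 fell and 15 did neither (11 and 3 adjusted over the list alone). For hypoxia targets, camera gave adjusted p = 0.00137 (0.499 with an estimated correlation). INSIG2 rose from 44.4 ± 3.99 to 91.5 ± 2.999, and BNIP3L from 131 ± 11.5 to 221 ± 2.41. Of the 15 lipid absorption genes, 1 rose, 0 fell and 14 did neither (0 and 0 adjusted over the list alone). For lipid absorption genes, camera gave adjusted p = 0.0231 (0.499 with an estimated correlation). SCARB1, a lipoprotein receptor and the called member, rose from 55.8 ± 2.19 to 85.0 ± 3.73 FPKM. The lipid absorption call was lost without control replicate 3 (camera adjusted p up to 0.0678). By fry the adjusted p of these lists was, in the same order, 0.115, 0.185, 0.0589, 0.0834 and 0.0897. The metallothionein list did not pass fry either (0.0672), so 9 of the 15 lists that passed camera also passed fry.

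No shift passed camera in OTA against control for adherens junction and desmosome (1 higher and 1 lower of 19, 1 and 1 over the list), actin cytoskeleton (1 higher and 1 lower of 20, 0 and 1 over the list) and brush border (3 higher and 3 lower of 19, 4 and 3 over the list). The same held for fatty acid oxidation (0 higher and 1 lower of 19, 0 and 1 over the list), nutrient and ion transporters (0 higher and 2 lower of 17, 0 and 1 over the list) and xenobiotic metabolism and efflux (1 higher and 2 lower of 26, 1 and 2 over the list). Nor did a test pass for NRF2 targets (0 higher and 6 lower of 22, 1 and 7 over the list), aminoacyl-tRNA synthetases (0 higher and 2 lower of 20, 0 and 1 over the list) and bacterial sensing and antimicrobial (1 higher and 2 lower of 13, 1 and 2 over the list). Also not past the test were mitosis (0 higher and 3 lower of 24, 0 and 0 over the list), DNA replication (2 higher and 3 lower of 23, 2 and 3 over the list) and cholesterol synthesis and uptake (3 higher and 4 lower of 24, 4 and 4 over the list). Below the threshold too were histones with polyadenylated transcripts (0 higher and 4 lower of 13, 0 and 4 over the list), mesenchymal transition and TGF-beta (3 higher and 3 lower of 12, 3 and 3 over the list) and mucins and goblet cell (1 higher and 1 lower of 9, 1 and 1 over the list). The last lists without a pass were crypt stem cell and Wnt (1 higher and 3 lower of 15, 1 and 3 over the list), autophagy and lysosome (1 higher and 5 lower of 20, 2 and 7 over the list) and other cell types, stromal immune and endothelial (0 higher and 0 lower of 8, 2 and 0 over the list). The median, the mean and the test of the actin cytoskeleton, NRF2 target, bacterial sensing, cholesterol and mesenchymal lists did not all have the same sign. By fry the polyadenylated histone and mesenchymal lists were lower (adjusted p = 0.0315 and 0.00817). Over all genes, 623 were called higher and 1665 lower, 803 of them by at least 1 on the log2 scale. In 6469 genes (50.04%, where chance gives 10%) the OTA libraries did not overlap the controls. The share of calls that were higher was 27.2% as deposited and 46.2% after median-centring (1153 higher, 1342 lower), which moved the median of all genes by 0.105. It was 40.2% after quantile normalization (976 and 1454) and 42.7% with upper-quartile scaling (1016 and 1362). The count of 2288 became 1467 and 1346 without control replicate 2 and 3, 1299 without OTA replicate 3 and 4364 without combined replicate 3. Of 74 named genes called, 54 kept their call in each alternative that tested them. The others were HIST2H3A, HIST2H2BF, HIST1H2AJ, HIST2H2AB, RUSC1-AS1, SCARB1, MT1X, BIK, IRF1, OASL, LOX, PFKFB4, LDHA, PFKM, NDUFAB1, NDUFV1, SDHC, RPL9, RPS2 and CLDN3.

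**Figure D3:**
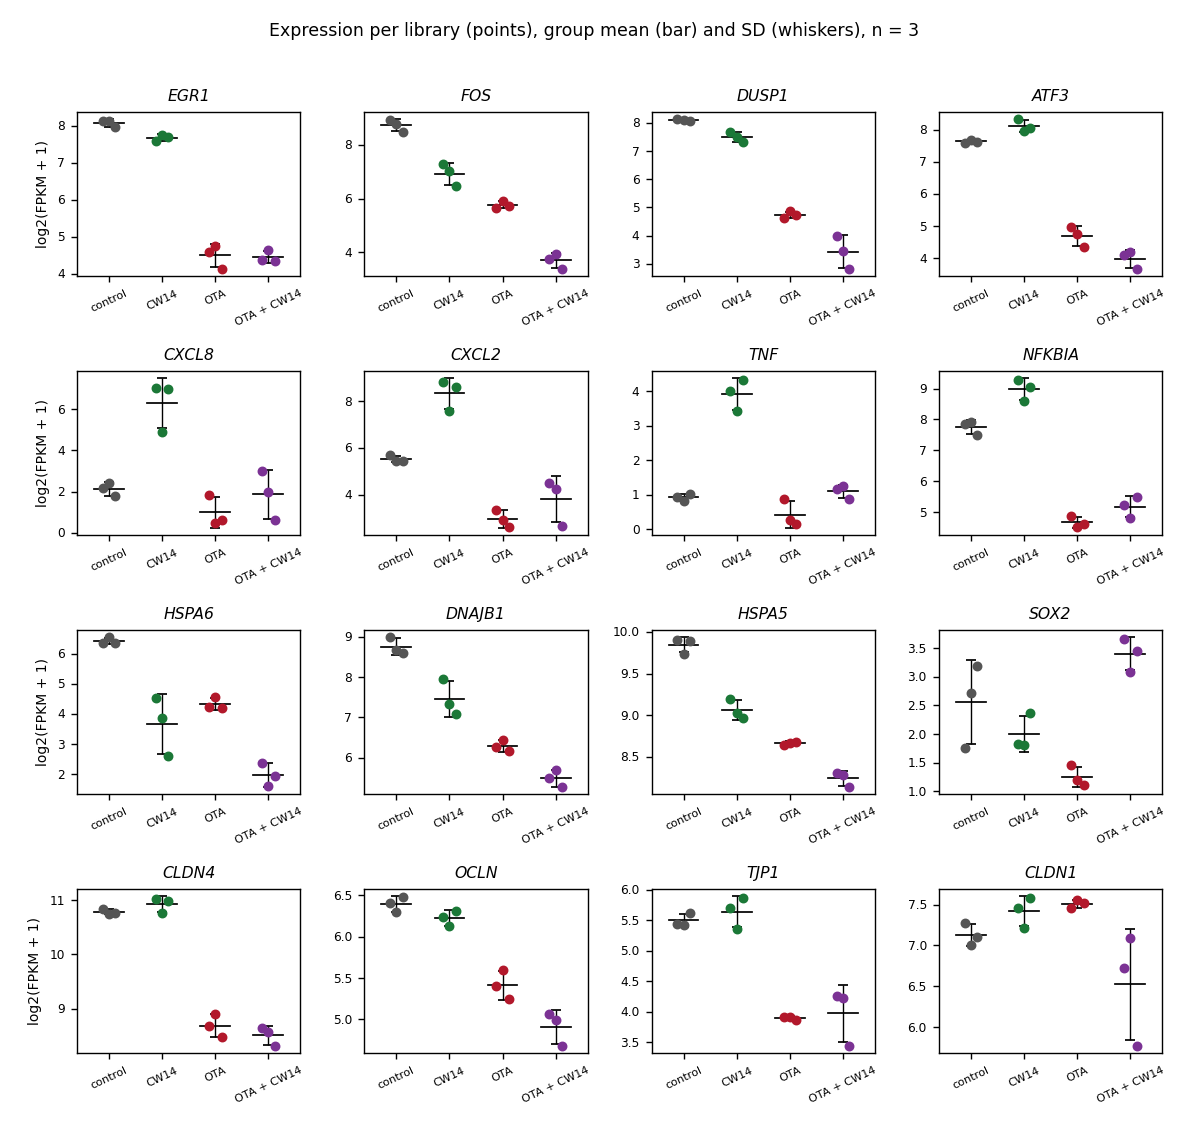
log2(FPKM + 1) of 16 named genes in each library (points), with the group mean (long bar) and SD (whiskers), n = 3 per group. EGR1, DUSP1 and CLDN4 are low in both groups with OTA. TNF is highest with CW14 alone (14.6 ± 4.69 FPKM).

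CW14 against control asks what the bacteria alone did. Few genes changed, and most of the largest rises were inflammatory cytokines. CXCL8, the neutrophil chemokine interleukin-8 (chromosome 4, 74606221 to 74609433), rose from 3.43 ± 0.967 to 93.2 ± 55.9 FPKM (log2 difference 4.16, SE 0.64, limma adjusted p = 0.0149). TNF (chromosome 6, 31543342 to 31546112) rose from 0.902 ± 0.135 to 14.6 ± 4.69 (log2 difference 2.99, SE 0.26, limma adjusted p = 0.000854). CXCL1 rose from 36.8 ± 5.77 to 260.0 ± 145, and CXCL2 from 45.5 ± 4.41 to 341 ± 134. CXCL3 rose from 9.81 ± 1.01 to 82.3 ± 41.9, and LTB from 1.79 ± 1.02 to 18.4 ± 5.93. PLAU, which encodes urokinase, rose from 2.16 ± 0.442 to 22.02 ± 10.8 FPKM. CXCL10 had control values of 0.870 ± 0.637 and 17.3 ± 7.68 with CW14. CSF3 had control values of 0.335 ± 0.301 and 7.96 ± 4.18 with CW14. CSF2 (chromosome 5, 131409483 to 131411863) was listed at 0 in the 3 controls and at 6.02 ± 2.68 with CW14. Of the 26 NF-kB and inflammatory cytokine genes, 13 rose, 0 fell and 13 did neither (22 and 0 adjusted over the list alone). Their median log2 difference was 1.56. For NF-kB and inflammatory cytokine genes, camera gave adjusted p = 9.33e-47 (0.0173 with an estimated correlation).

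Some chaperone genes fell with CW14. Of the 16 heat shock proteins, 0 rose, 7 fell and 9 did neither (0 and 13 adjusted over the list alone). For heat shock proteins, camera gave adjusted p = 4.18e-23 (0.0115 with an estimated correlation). HSPA6 (chromosome 1, 161494328 to 161496687) fell from 84.7 ± 6.75 to 13.6 ± 8.62 (log2 difference -2.75, SE 0.38, limma adjusted p = 0.00866). DNAJB1 fell from 436 ± 64.0 to 182 ± 58.8, and HSPA1A from 1182 ± 199 to 526 ± 180.2. HSPH1 fell from 48.0 ± 2.70 to 21.8 ± 4.63 FPKM. HSPA7, a close copy of HSPA6 that can share its fragments, fell from 11.4 ± 0.171 to 2.67 ± 1.35 FPKM. Of the 22 unfolded protein response genes, 0 rose, 1 fell and 21 did neither (0 and 6 adjusted over the list alone). For unfolded protein response genes, camera gave adjusted p = 8.32e-08 (0.021 with an estimated correlation). HSPA5, an endoplasmic reticulum chaperone and the called member, fell from 919 ± 56.9 to 536 ± 44.1 FPKM. FOS fell from 427 ± 64.7 to 124 ± 33.9, and RGS2 from 68.4 ± 11.7 to 18.9 ± 2.46. ID1 fell from 315 ± 20.2 to 106 ± 38.4, and COX20 from 30.2 ± 10.99 to 10.1 ± 2.18. ADM, a vasoactive peptide gene, fell from 111 ± 6.22 to 40.8 ± 6.16 FPKM. HIST1H2AH, one of a family of near-identical copies, was listed at 0 in the 3 CW14 libraries, with control values of 4.91 ± 2.19. TBC1D3F, of another such family and with a locus that spans many copies, was also listed at 0 in the 3 CW14 libraries, with control values of 3.74 ± 0.204.

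Other lists passed in CW14 against control by small shifts in which few or no members were called. ATF4 and integrated stress response genes shifted down, with 0 higher and 0 lower of 22 (0 and 5 adjusted over the list alone). For ATF4 and integrated stress response genes, camera gave adjusted p = 5.43e-06 (0.246 with an estimated correlation). Aminoacyl-tRNA synthetases shifted down, with 0 higher and 0 lower of 20 (0 and 1 adjusted over the list alone). For aminoacyl-tRNA synthetases, camera gave adjusted p = 0.000714 (0.542 with an estimated correlation). Histones with polyadenylated transcripts shifted down, with 0 higher and 0 lower of 13 (0 and 3 adjusted over the list alone). For histones with polyadenylated transcripts, camera gave adjusted p = 0.000146 (0.0522 with an estimated correlation). NRF2 targets shifted down, with 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone). For NRF2 targets, camera gave adjusted p = 0.0046 (0.509 with an estimated correlation). Another 5 passed only while certain libraries were in. Ribosomal protein genes shifted down, with 0 higher and 0 lower of 55 (0 and 0 adjusted over the list alone). For ribosomal protein genes, camera gave adjusted p = 0.00211 (0.674 with an estimated correlation). The ribosomal protein call was lost without control replicate 1 or CW14 replicate 3 (camera adjusted p up to 0.222). Mitosis genes shifted down, with 0 higher and 0 lower of 24 (0 and 0 adjusted over the list alone). For mitosis genes, camera gave adjusted p = 0.0177 (0.496 with an estimated correlation). The mitosis call was lost without control replicate 1 or CW14 replicate 1 (camera adjusted p up to 0.271). DNA replication genes shifted down, with 0 higher and 0 lower of 23 (0 and 0 adjusted over the list alone). For DNA replication genes, camera gave adjusted p = 0.00373 (0.496 with an estimated correlation). The DNA replication call was lost without CW14 replicate 2 (camera adjusted p up to 0.148). Hypoxia targets shifted up, with 0 higher and 1 lower of 27 (0 and 1 adjusted over the list alone), the called one being ADM. For hypoxia targets, camera gave adjusted p = 0.0046 (0.542 with an estimated correlation). The hypoxia call was lost without control replicate 3 or CW14 replicate 2 (camera adjusted p up to 0.472). Immediate early and MAPK genes shifted down, with 0 higher and 2 lower of 34 (4 and 7 adjusted over the list alone), the called ones being FOS and DUSP2. For immediate early and MAPK genes, camera gave adjusted p = 0.0356 (0.542 with an estimated correlation). The immediate early call was lost without control replicate 1, CW14 replicate 2, combined replicate 2 or combined replicate 3 (camera adjusted p up to 0.18). With the GC content and length trend removed, the immediate early and mitosis lists did not pass (camera adjusted p = 0.138 and 0.0691). Of the lists in this paragraph, the histones alone passed fry.

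The junction genes named here were not called with CW14 alone. CLDN4 stood at 1770.1 ± 60.7 in control and 1956 ± 189 with CW14. OCLN stood at 83.4 ± 5.36 in control and 74.1 ± 4.76 with CW14. TJP1 stood at 44.3 ± 3.57 in control and 49.3 ± 8.53 with CW14. The log2 differences of CLDN1, CLDN2, CLDN3, F11R, CDH1 and MYLK were 0.29, -0.05, -0.08, 0.00, 0.04 and 0.22. Of the 28 tight junction genes 0 were called, and 0 adjusted over the list alone (limma; camera adjusted p = 0.186). The log2 differences went with transcript length (rho = 0.234) more than with GC content (rho = -0.0343). In all, 28 genes were called higher and 19 lower, and 858 had an unadjusted p under 0.05. In 2653 genes (20.5%, where chance gives 10%) the groups did not overlap. The count of 47 depended on single libraries. It was 4, 9 and 7 without control replicate 1, 2 and 3, and 21 and 11 without CW14 replicate 1 and 3. It was 27 and 30 without OTA replicate 1 and 3, 123 without combined replicate 3, and 25 with no filter on low values. Of 24 named genes called, TNF, CSF2 and ADM kept their call in each alternative that tested them.

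**Figure D4:**
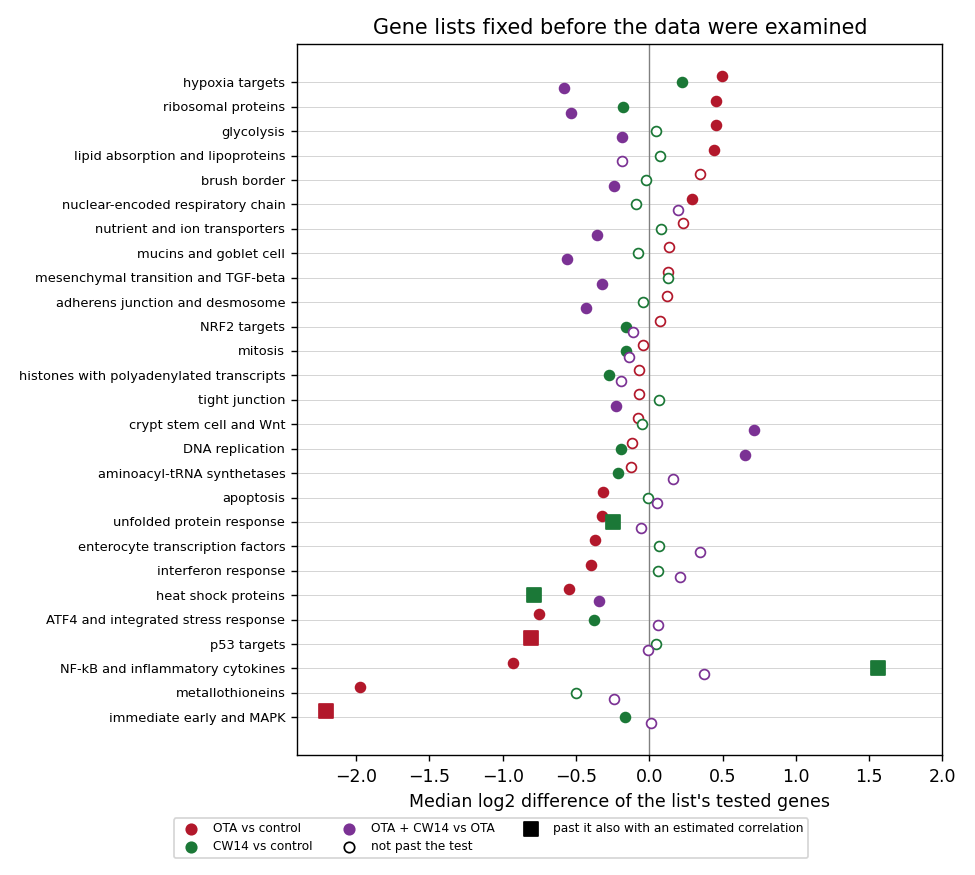
Median log2 difference of the lists that passed in at least 1 of the comparisons shown, for OTA, CW14 and the combined group against OTA. Filled points passed camera with a preset correlation, and squares also with an estimated one, such as immediate early genes with OTA (-2.21) and NF-kB genes with CW14 (1.56).

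The combined group against OTA asks what adding CW14 to the toxin did. Of the 12 lists that passed camera, 2 shifted up and 10 down. All 12 still passed once the GC content and length trend was removed, 10 passed fry (not glycolysis and ribosomal proteins) and 0 passed with an estimated correlation. SOX2, a stem cell transcription factor (deposited locus chromosome 3, 180774466 to 181460013, which spans other genes), rose from 1.39 ± 0.301 to 9.73 ± 2.09 FPKM (log2 difference 2.15, SE 0.32, limma adjusted p = 0.00297). CD3EAP, a subunit of RNA polymerase I, rose from 2.21 ± 0.733 to 11.4 ± 3.38 FPKM. Of the 23 DNA replication genes, 14 rose, 0 fell and 9 did neither (15 and 0 adjusted over the list alone). For DNA replication genes, camera gave adjusted p = 6.3e-06 (0.205 with an estimated correlation). FEN1 rose from 30.4 ± 1.65 to 67.7 ± 4.66, and MCM3 from 19.2 ± 0.6001 to 41.3 ± 12.5. Of the 15 crypt stem cell and Wnt genes, 5 rose, 0 fell and 10 did neither (7 and 0 adjusted over the list alone). For crypt stem cell and Wnt genes, camera gave adjusted p = 9.34e-05 (0.205 with an estimated correlation). ASCL2 rose from 18.2 ± 3.30 to 41.4 ± 6.12, and RNF43 from 8.41 ± 1.20 to 17.1 ± 1.78. The interferon-induced genes IFI6 and IFI27 rose from 7.29 ± 2.30 to 31.8 ± 15.9 and from 2.46 ± 0.869 to 12.05 ± 4.56. IFITM3 had values of 5.77, 0 and 1.53 with OTA and 14.5 ± 7.52 in the combined group. The interferon list did not pass (camera adjusted p = 0.292). TMEM183B had values of 5.12, 0.00434 and 2.26 with OTA and 11.03 ± 2.002 in the combined group. PLAU rose from 0.656 ± 0.592 to 5.19 ± 2.23 FPKM. CDK3 rose from 2.22 ± 1.57 to 11.3 ± 9.57, and WNT6 from 1.69 ± 0.952 to 8.23 ± 3.35. The antisense gene IBA57-AS1 was listed at 0 in the 3 OTA libraries and at 3.10 ± 2.04 in the combined group. These differences went with transcript GC content, which correlated with the log2 difference at rho = 0.450 across genes, against 0.0356 in OTA against control. With transcript length rho was -0.175, against -0.136 in OTA against control. The median GC content was 56.3% in genes called higher and 42.3% in those called lower.

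**Figure D5:**
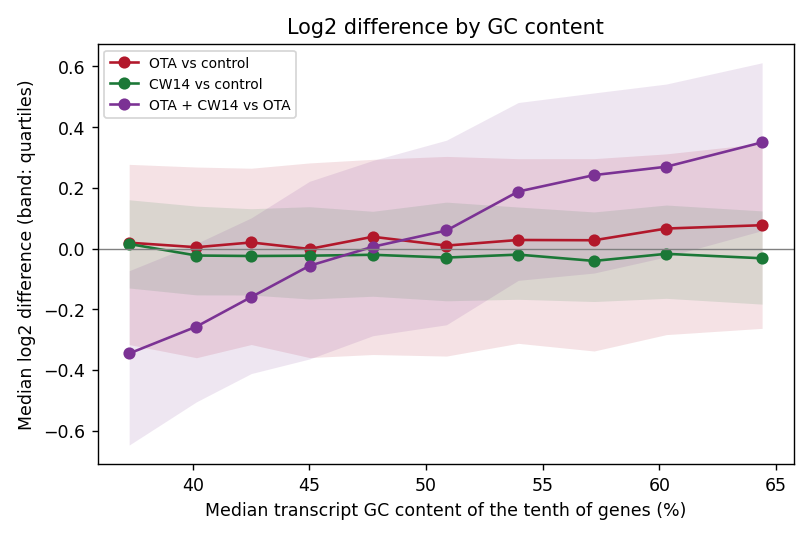
Median log2 difference (lines; bands are quartiles of genes) in 10 equal bins of the tested genes by transcript GC content in percent. The combined group against OTA rises with GC content (rho = 0.450), while OTA against control does not (rho = 0.0356).

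Some hypoxia, ribosomal protein and chaperone genes were lower in the combined group than with OTA alone. Of the 27 hypoxia targets, 0 rose, 11 fell and 16 did neither (0 and 17 adjusted over the list alone). For hypoxia targets, camera gave adjusted p = 3.57e-09 (0.205 with an estimated correlation). CA9, a carbonic anhydrase (chromosome 9, 35673913 to 35681154), fell from 25.2 ± 2.94 to 6.38 ± 1.84 (log2 difference -1.85, SE 0.20, limma adjusted p = 0.00158). INSIG2 fell from 91.5 ± 2.999 to 30.5 ± 5.83, and MXI1 from 82.1 ± 13.8 to 32.8 ± 4.87. Of the 55 ribosomal protein genes, 0 rose, 14 fell and 41 did neither (0 and 19 adjusted over the list alone). For ribosomal protein genes, camera gave adjusted p = 2.05e-08 (0.55 with an estimated correlation). RPL30 fell from 254 ± 30.3 to 102 ± 16.4, and RPL3 from 766 ± 25.4 to 385 ± 18.6. Of the 16 heat shock proteins, 0 rose, 5 fell and 11 did neither (1 and 8 adjusted over the list alone). For heat shock proteins, camera gave adjusted p = 0.0096 (0.437 with an estimated correlation). The heat shock call was lost without combined replicate 2 (camera adjusted p up to 0.0601). HSPA6 fell from 19.3 ± 2.91 to 3.03 ± 1.11, and HSPA8 from 1338 ± 41.3 to 829 ± 52.8. FOS fell from 53.7 ± 4.88 to 12.2 ± 2.53 FPKM. Of the 18 glycolysis genes, 0 rose, 3 fell and 15 did neither (0 and 3 adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 0.0467 (0.669 with an estimated correlation). HK2, which phosphorylates glucose, fell from 43.4 ± 7.20 to 19.0 ± 3.66 FPKM. The glycolysis call was lost without OTA replicate 1, combined replicate 1 or combined replicate 2 (camera adjusted p up to 0.535). SLC3A1, a subunit of a cystine transporter, had values of 16.0 ± 2.46 with OTA and 4.83, 3.604 and 0 in the combined group. UGT2A3 fell from 43.2 ± 9.88 to 11.7 ± 6.58, and CP from 20.04 ± 5.94 to 5.10 ± 0.812. HIST1H4B fell from 17.2 ± 10.7 to 3.14 ± 1.05, and HIST3H2BB from 16.8 ± 2.45 to 4.67 ± 2.90. HIST1H4D had values of 9.40 ± 0.998 with OTA and 0, 6.01 and 0 in the combined group, and HIST1H4H of 8.96 ± 1.16 and 2.000, 5.74 and 0.

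Of junction, brush border, transporter and mucin genes, a minority were lower in the combined group than with OTA alone. Of the 28 tight junction genes, 0 rose, 4 fell and 24 did neither (0 and 4 adjusted over the list alone). For tight junction genes, camera gave adjusted p = 0.00658 (0.205 with an estimated correlation). CLDN1 fell from 181 ± 6.37 to 97.6 ± 41.0, and PRKCI from 42.0 ± 4.22 to 24.3 ± 6.62. OCLN fell further, from 41.8 ± 5.24 to 29.3 ± 4.12 (log2 difference -0.50, SE 0.14, limma adjusted p = 0.0312). CLDN4, at 412 ± 60.7 with OTA and 364 ± 42.6 in the combined group, was not called, nor was TJP1, at 13.9 ± 0.269 and 15.3 ± 4.68. The log2 differences of CLDN2, CLDN3, F11R and MYLK, also not called, were 0.10, 0.26, -0.18 and -0.31. Of the 19 adherens junction and desmosome genes, 0 rose, 6 fell and 13 did neither (0 and 10 adjusted over the list alone). For adherens junction and desmosome genes, camera gave adjusted p = 0.000168 (0.205 with an estimated correlation). CDH17 fell from 377 ± 20.3 to 211 ± 6.98, and EPCAM from 682 ± 25.3 to 439 ± 52.1. DSG2 fell from 80.3 ± 6.70 to 39.1 ± 9.45, and CDH1 from 333 ± 16.1 to 243 ± 33.9. Of the 19 brush border genes, 0 rose, 7 fell and 12 did neither (0 and 7 adjusted over the list alone). For brush border genes, camera gave adjusted p = 0.00293 (0.437 with an estimated correlation). The brush border call was lost without combined replicate 2 (camera adjusted p up to 0.058). MEP1A, a brush border protease, fell from 68.4 ± 12.9 to 27.0 ± 3.99 FPKM. Of the 17 nutrient and ion transporters, 0 rose, 4 fell and 13 did neither (0 and 4 adjusted over the list alone). For nutrient and ion transporters, camera gave adjusted p = 0.00627 (0.205 with an estimated correlation). SLC11A2, an iron transporter, fell from 459 ± 79.3 to 204 ± 61.8 FPKM. Of the 9 mucin and goblet cell genes, 1 rose, 3 fell and 5 did neither (1 and 3 adjusted over the list alone). For mucin and goblet cell genes, camera gave adjusted p = 0.022 (0.55 with an estimated correlation). The mucin call was lost without combined replicate 1 or combined replicate 2 (camera adjusted p up to 0.14). MUC13 fell from 159 ± 11.4 to 69.9 ± 6.90, and MUC17 from 9.91 ± 3.05 to 2.64 ± 1.13. Of the 12 mesenchymal transition genes, 0 rose, 4 fell and 8 did neither (0 and 4 adjusted over the list alone). For mesenchymal transition genes, camera gave adjusted p = 0.0371 (0.205 with an estimated correlation). ITGAV, an integrin subunit, fell from 37.6 ± 2.24 to 19.2 ± 8.92 FPKM. The mesenchymal call was lost without OTA replicate 1, OTA replicate 2, combined replicate 1 or combined replicate 2 (camera adjusted p up to 0.0717).

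In all, 1007 genes were called higher and 1063 lower in the combined group against OTA, 484 of the 2070 by at least 1 on the log2 scale. In 4441 genes (34.4%, where chance gives 10%) the groups did not overlap. The share of calls that were higher was 48.6% as deposited and 36.7% after median-centring (774 higher, 1335 lower). Residual SD was 0.338 to 0.588 in the combined group and 0.305 to 0.367 elsewhere, so the spread shared by all 4 groups can lower these p-values. The count was 945, 653 and 753 without OTA replicate 1, 2 and 3, and 3388 without combined replicate 2. Of 64 named genes called, 13 kept their call in each alternative that tested them: SOX2, CD3EAP, HSPA6, FOS, CA9, CP, MEP1A, INSIG2, MXI1, RPL30, RPL3, FEN1 and MUC13.

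Some genes that OTA changed were called back the other way when CW14 was added. Of 2288 genes called with OTA, 176 had risen and were then lower in the combined group (51.2 for independent lists of these sizes), and 288 had fallen and were then higher (130 for independent lists). INSIG2 and RPL3 were among those 176. Of the 464 reversed genes, 383 were not called in the combined group against control, 61 were called in OTA's direction and 20 opposite. Of the 2288, 1428 were called there in OTA's direction. In the direction of OTA, 11 genes rose further and 101 fell further (48.5 and 137 for independent lists). Both comparisons share the OTA libraries, which alone makes their errors opposite, and the numbers for independent lists omit this. In 100 simulations with an OTA effect and none of CW14, the log2 differences correlated at -0.339 to -0.105 (mean -0.225, observed -0.281). Their covariance was -0.0900 to -0.0247 (mean -0.0514, observed -0.1001). These conflict and small RNA genes can sway both, so reversal stays open. The count of 464 became 32 with only the compared groups in each fit, 208 and 197 without control replicate 2 and 3, and 1114 without combined replicate 3. It was 206, 147 and 127 without OTA replicate 1, 2 and 3.

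In the combined group against control, most immediate early genes and some junction genes were lower, and the log2 differences followed GC content (rho = 0.400) and transcript length (rho = -0.250). FOS fell from 427 ± 64.7 to 12.2 ± 2.53 FPKM (log2 difference -5.03, SE 0.21, limma adjusted p = 1.02e-07). PCK1 fell from 131 ± 41.9 to 2.30 ± 1.05, and DUSP1 from 272 ± 6.86 to 10.4 ± 4.45. HSPA6 fell from 84.7 ± 6.75 to 3.03 ± 1.11, and DDIT4 from 1222 ± 84.7 to 57.9 ± 5.08. HIST1H2AL, HIST2H3A and KIAA1683 rose by 2.80, 2.63 and 2.21 on the log2 scale. Of the 34 immediate early and MAPK genes, 0 rose, 33 fell and 1 did neither (0 and 34 adjusted over the list alone). For immediate early and MAPK genes, camera gave adjusted p = 1.22e-30 (0.0113 with an estimated correlation). Of the 28 tight junction genes, 1 rose, 12 fell and 15 did neither (1 and 14 adjusted over the list alone). For tight junction genes, camera gave adjusted p = 0.000583 (0.15 with an estimated correlation). PARD6B fell from 98.3 ± 7.797 to 18.6 ± 4.70, and CLDN4 from 1770.1 ± 60.7 to 364 ± 42.6. TJP1 fell from 44.3 ± 3.57 to 15.3 ± 4.68, and OCLN from 83.4 ± 5.36 to 29.3 ± 4.12. F11R and MYLK fell by 0.42 and 0.54, and CLDN1, CLDN2, CLDN3 and CDH1 were not called (-0.60, 0.34, -0.54 and -0.25). Of the 46 nuclear-encoded respiratory chain genes, 13 rose, 0 fell and 33 did neither (13 and 0 adjusted over the list alone). For nuclear-encoded respiratory chain genes, camera gave adjusted p = 0.000331 (0.52 with an estimated correlation). Of the 23 DNA replication genes, 8 rose, 1 fell and 14 did neither (9 and 1 adjusted over the list alone). For DNA replication genes, camera gave adjusted p = 0.000914 (0.294 with an estimated correlation).

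The other lists that passed in this comparison were lower. Of the 19 adherens junction and desmosome genes, 0 rose, 5 fell and 14 did neither (0 and 6 over the list, camera adjusted p = 0.00709, 0.294 with an estimated correlation). Of the 22 ATF4 and integrated stress response genes, 1 rose, 13 fell and 8 did neither (1 and 13 over the list, camera adjusted p = 1.28e-06, 0.15 with an estimated correlation). Of the 22 unfolded protein response genes, 1 rose, 9 fell and 12 did neither (1 and 9 over the list, camera adjusted p = 0.0151, 0.289 with an estimated correlation). Of the 16 heat shock proteins, 0 rose, 10 fell and 6 did neither (0 and 10 over the list, camera adjusted p = 3.33e-05, 0.15 with an estimated correlation). Of the 6 metallothionein and zinc genes, 0 rose, 4 fell and 2 did neither (0 and 4 over the list, camera adjusted p = 0.0151, 0.501 with an estimated correlation). Of the 25 p53 targets, 0 rose, 13 fell and 12 did neither (1 and 13 over the list, camera adjusted p = 4.91e-05, 0.0616 with an estimated correlation). Of the 24 apoptosis genes, 1 rose, 9 fell and 14 did neither (1 and 10 over the list, camera adjusted p = 0.00555, 0.15 with an estimated correlation). Of the 26 NF-kB and inflammatory cytokine genes, 0 rose, 12 fell and 14 did neither (0 and 12 over the list, camera adjusted p = 0.000331, 0.501 with an estimated correlation). Of the 27 hypoxia targets, 0 rose, 9 fell and 18 did neither (0 and 10 over the list, camera adjusted p = 0.00836, 0.501 with an estimated correlation). Of the 20 autophagy and lysosome genes, 2 rose, 10 fell and 8 did neither (3 and 11 over the list, camera adjusted p = 0.049, 0.501 with an estimated correlation). Without combined replicate 2 the unfolded protein response and metallothionein calls were lost (camera adjusted p = 0.0837 and 0.0671). The autophagy call was lost without control replicate 3, OTA replicate 2, OTA replicate 3, combined replicate 1 or combined replicate 2 (camera adjusted p up to 0.223). In all, 1557 genes were called higher and 2172 lower. The share that was higher was 41.8% as deposited and 54.9% with upper-quartile scaling (2160 higher, 1777 lower). The count of 3729 became 1596 with only these groups in the fit and 2265 without control replicate 1.

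The combined group against CW14 asks what the toxin did in the presence of the bacteria. Most cytokine genes were lower, and the log2 differences followed GC content (rho = 0.393) and transcript length (rho = -0.321). Of the 26 NF-kB and inflammatory cytokine genes, 0 rose, 23 fell and 3 did neither (0 and 24 adjusted over the list alone). For NF-kB and inflammatory cytokine genes, camera gave adjusted p = 6.82e-17 (0.15 with an estimated correlation). CXCL8 fell from 93.2 ± 55.9 to 3.51 ± 3.31 FPKM (log2 difference -4.42, SE 0.64, limma adjusted p = 0.000448). CXCL1 fell from 260.0 ± 145 to 9.66 ± 4.53, and CXCL2 from 341 ± 134 to 14.99 ± 8.47. Of the 34 immediate early and MAPK genes, 0 rose, 33 fell and 1 did neither (0 and 33 adjusted over the list alone). For immediate early and MAPK genes, camera gave adjusted p = 5.2e-28 (0.0153 with an estimated correlation). Of the 28 tight junction genes, 0 rose, 16 fell and 12 did neither (0 and 16 adjusted over the list alone). For tight junction genes, camera gave adjusted p = 5.46e-05 (0.101 with an estimated correlation). PCK1 and BTG2 fell by 4.95 and 4.44 on the log2 scale, and HIST1H2AL, FAM156B and CST1 rose by 3.27, 3.03 and 2.79. CLDN1, CLDN4, OCLN, TJP1, F11R and MYLK fell (-0.89, -2.43, -1.32, -1.66, -0.42 and -0.76). CLDN2, CLDN3 and CDH1 were not called (0.39, -0.47 and -0.29).

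Other lists also passed against CW14. Of the 19 adherens junction and desmosome genes, 0 rose, 6 fell and 13 did neither (0 and 6 over the list, camera adjusted p = 0.012, 0.31 with an estimated correlation). Of the 18 enterocyte transcription factors, 0 rose, 8 fell and 10 did neither (0 and 8 over the list, camera adjusted p = 0.0451, 0.31 with an estimated correlation). Of the 22 ATF4 and integrated stress response genes, 3 rose, 11 fell and 8 did neither (3 and 11 over the list, camera adjusted p = 0.000369, 0.31 with an estimated correlation). Of the 20 aminoacyl-tRNA synthetases, 4 rose, 0 fell and 16 did neither (4 and 0 over the list, camera adjusted p = 0.0216, 0.685 with an estimated correlation). Of the 25 p53 targets, 1 rose, 13 fell and 11 did neither (1 and 13 over the list, camera adjusted p = 3.28e-05, 0.0588 with an estimated correlation). Of the 24 apoptosis genes, 2 rose, 9 fell and 13 did neither (2 and 10 over the list, camera adjusted p = 0.0101, 0.161 with an estimated correlation). Of the 27 hypoxia targets, 1 rose, 12 fell and 14 did neither (1 and 14 over the list, camera adjusted p = 6.87e-05, 0.31 with an estimated correlation). Of the 46 nuclear-encoded respiratory chain genes, 19 rose, 0 fell and 27 did neither (20 and 0 over the list, camera adjusted p = 1.7e-05, 0.534 with an estimated correlation). Of the 23 DNA replication genes, 14 rose, 1 fell and 8 did neither (17 and 1 over the list, camera adjusted p = 1.7e-05, 0.161 with an estimated correlation). Of the 15 crypt stem cell and Wnt genes, 7 rose, 1 fell and 7 did neither (8 and 1 over the list, camera adjusted p = 0.0446, 0.529 with an estimated correlation). The enterocyte transcription factor call was lost without CW14 replicate 1, CW14 replicate 3, combined replicate 1 or combined replicate 3 (camera adjusted p up to 0.102). The aminoacyl-tRNA synthetase call was lost without CW14 replicate 1 or combined replicate 3 (up to 0.155), and the crypt and Wnt call without CW14 replicate 1, CW14 replicate 2, combined replicate 1 or combined replicate 2 (up to 0.114). In all, 1919 genes were called higher and 2260 lower. The count of 4179 became 1521 with only these groups in the fit and 2780 without CW14 replicate 2.

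The interaction tests whether the effect of CW14 differed with and without OTA. Some cytokine genes had a negative one. Of the 26 NF-kB and inflammatory cytokine genes, 0 had a positive interaction, 8 a negative one and 18 had neither (0 and 19 adjusted over the list alone). For NF-kB and inflammatory cytokine genes, camera gave adjusted p = 1.06e-10 (0.202 with an estimated correlation). TNF stood at 0.902 ± 0.135 FPKM in control, 14.6 ± 4.69 with CW14, 0.381 ± 0.389 with OTA and 1.15 ± 0.2797 in the combined group (interaction -2.33, SE 0.36, limma adjusted p = 0.0164). LTB stood at 1.79 ± 1.02, 18.4 ± 5.93, 2.76 ± 2.52 and 2.44 ± 0.541 in the same order. CSF2 was listed at 0 in the 3 control and the 3 combined libraries, with OTA values of 0.642, 0.523 and 0. The interaction of CXCL8 was not called (limma adjusted p = 0.0627). Of the 27 hypoxia targets, 0 had a positive interaction, 9 a negative one and 18 had neither (1 and 15 adjusted over the list alone). For hypoxia targets, camera gave adjusted p = 3.66e-10 (0.202 with an estimated correlation). Of the 23 DNA replication genes, 4 had a positive interaction, 0 a negative one and 19 had neither (15 and 0 adjusted over the list alone). For DNA replication genes, camera gave adjusted p = 1.65e-07 (0.202 with an estimated correlation). FEN1 stood at 45.8 ± 6.60 in control, 42.5 ± 2.07 with CW14, 30.4 ± 1.65 with OTA and 67.7 ± 4.66 in the combined group. SOX2, DKK1, NUPR1, POMC and the antisense gene RASSF1-AS1, which cannot be told from its partner strand, had the largest positive interactions. The interactions of CLDN1, CLDN2, CLDN3, CLDN4, OCLN, TJP1, F11R, CDH1 and MYLK were not called (-1.28, 0.16, 0.33, -0.31, -0.33, -0.07, -0.18, -0.50 and -0.53).

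The interaction also followed transcript GC content (rho = 0.393 across genes) and length (rho = -0.2396). Other lists passed as well. Of the 28 tight junction genes, 0 had a positive interaction, 1 a negative one and 27 had neither (0 and 1 over the list, camera adjusted p = 0.00314, 0.202 with an estimated correlation). Of the 19 adherens junction and desmosome genes, 0 had a positive interaction, 1 a negative one and 18 had neither (0 and 4 over the list, camera adjusted p = 0.00125, 0.202 with an estimated correlation). Of the 19 brush border genes, 0 had a positive interaction, 0 a negative one and 19 had neither (0 and 7 over the list, camera adjusted p = 0.00408, 0.42 with an estimated correlation). Of the 17 nutrient and ion transporters, 0 had a positive interaction, 1 a negative one and 16 had neither (0 and 3 over the list, camera adjusted p = 0.0054, 0.202 with an estimated correlation). Of the 20 aminoacyl-tRNA synthetases, 2 had a positive interaction, 0 a negative one and 18 had neither (2 and 0 over the list, camera adjusted p = 0.00364, 0.695 with an estimated correlation). Of the 16 heat shock proteins, 2 had a positive interaction, 0 a negative one and 14 had neither (2 and 0 over the list, camera adjusted p = 0.00592, 0.405 with an estimated correlation). Of the 18 glycolysis genes, 0 had a positive interaction, 1 a negative one and 17 had neither (0 and 1 over the list, camera adjusted p = 0.039, 0.73 with an estimated correlation). Of the 55 ribosomal protein genes, 0 had a positive interaction, 2 a negative one and 53 had neither (0 and 2 over the list, camera adjusted p = 0.00122, 0.73 with an estimated correlation). Of the 15 crypt stem cell and Wnt genes, 2 had a positive interaction, 0 a negative one and 13 had neither (3 and 0 over the list, camera adjusted p = 0.000257, 0.202 with an estimated correlation). Without combined replicate 2 the brush border and ribosomal protein calls were lost (camera adjusted p = 0.0586 and 0.1). The glycolysis call was lost without CW14 replicate 2, OTA replicate 1, combined replicate 1 or combined replicate 2 (up to 0.437). Brush border, aminoacyl-tRNA synthetase, glycolysis and ribosomal protein lists did not pass fry (adjusted p = 0.088, 0.171, 0.416 and 0.416). Over all genes, 239 had a positive interaction and 192 a negative one. The share that was positive was 55.5% as deposited and 39.5% after median-centring (171 positive, 262 negative). The count of 431 moved with every library. It was 250, 19 and 17 without control replicate 1, 2 and 3, and 93, 154 and 247 without CW14 replicate 1, 2 and 3. It was 81, 34 and 66 without OTA replicate 1, 2 and 3, and 184, 1521 and 1595 without combined replicate 1, 2 and 3. Of 31 named genes called, DKK1, CSF2 and INSIG2 kept their call in each alternative that tested them.

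The OTA effects without and with CW14, which share no library, had a Pearson correlation of 0.460 across the 12928 genes (Spearman 0.428). In both, 185 genes were higher (92.5 for independent lists) and 1076 lower (291), with 61 in opposite directions (356). The CW14 effects without and with OTA had a Pearson correlation of -0.0799 (Spearman -0.115), smaller in size than its jackknife spread of 0.108. It was -0.0340, -0.0494, -0.0354, -0.137, -0.0483 and -0.0361 without control replicate 3, CW14 replicate 1, 2 and 3, OTA replicate 3 and combined replicate 3. There 6 genes were higher in both (2.18), 10 lower in both (1.56) and 1 in opposite directions (3.78). Genes are not independent replicates in such correlations.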

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

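The results below were chosen because the effect of CW14 differed between cells without and with OTA, by the interaction test in limma. Of the tests in this part, the rank correlation without combined replicate 3, the tests with the GC content and length trend removed, the genes called in both CW14 effects and the labellings of libraries were chosen only after the results were seen. Values are interaction coefficients on the log2(FPKM + 1) scale, positive where CW14 did more upward with OTA than without. Negative values were found for the cytokine genes CSF2 (-3.18), CXCL10 (-3.04), LTB (-2.76), CXCL3 (-2.67), CSF3 (-2.63) and TNF (-2.33), of which CSF2, CXCL10 and CSF3 were listed at 0 in some libraries. Hypoxia and glycolysis genes were negative too: INSIG2 (-2.05), CA9 (-1.74), HK2 (-1.62), MXI1 (-1.59), BNIP3L (-1.42) and PFKFB4 (-0.94). So were the epithelial genes MUC17 (-1.86), SLC11A2 (-1.60), MUC13 (-1.09) and CDH17 (-0.77), the stress genes ATF3 (-1.20) and GADD45A (-1.13) and the ribosomal protein genes RPL9 (-1.65) and RPL3 (-0.91). Positive values were found for the ranked genes SOX2 (2.71), DKK1 (2.65), NUPR1 (2.34), POMC (2.19) and RASSF1-AS1 (2.17), of which NUPR1 was listed at 0 in some libraries. The DNA replication genes MCM3 (1.28), CDC6 (1.25), FEN1 (1.23) and MCM4 (0.83) and the crypt genes ASCL2 (1.35) and RNF43 (0.99) were positive. The aminoacyl-tRNA synthetase genes FARSA (1.88) and WARS (1.00) and the chaperone genes HSPB1 (1.66) and DNAJA1 (0.97) were positive as well. The remaining positive ones were CD3EAP (1.98), SERTAD1 (1.80), ID1 (1.67), FOXA2 (1.58) and DUSP2 (1.22), named in other comparisons.

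Lists passed camera in the interaction as well. Median coefficients were -1.40 for NF-kB and inflammatory cytokines, -0.90 for hypoxia targets, -0.50 for adherens junctions and desmosomes, -0.46 for nutrient and ion transporters and -0.34 for the brush border. They were -0.30 for tight junctions, -0.29 for ribosomal proteins and -0.25 for glycolysis. Positive medians were 0.83 for DNA replication, 0.77 for crypt stem cell and Wnt genes, 0.44 for aminoacyl-tRNA synthetases and 0.44 for heat shock proteins. None of the 12 lists passed with an estimated correlation, and 8 of the 12 also passed by fry.

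Other splits of the libraries were run for each count. For the 12 libraries, 100 random regroupings were made, the real one included. Of these, 1 gave as many genes that differed among the 4 groups (4845, highest other 105). A chance labelling of these libraries can be excluded for that count. A chance difference between cultures or preparations cannot, since the replicates may be technical. Of the same regroupings 1 gave as many with an interaction (431, highest other 3) and 1 as many reversed genes (464, highest other 6). They mix libraries with and without OTA, so they do not test an interaction or a reversal given an effect of OTA, which stays open, and the interaction count was 19 and 17 without control replicate 2 and 3. For the lists that passed in the interaction, 20 of 100 gave as many (12, highest other 17), so chance cannot be excluded for that count. The 10 splits of 6 libraries are too few for a share under 0.05. As many genes were called in 1 of 10 splits for OTA against control (2288, highest other 1), for CW14 against control (47, highest other 1), for the combined group against OTA (2070, highest other 2), against control (3729, highest other 1) and against CW14 (4179, highest other 1). As many lists passed in 2 of 10 splits for OTA against control (15, highest other 17), 4 of 10 for CW14 against control (12, highest other 14) and 2 of 10 for the combined group against OTA (12, highest other 14). Against control it was 1 of 10 (14, highest other 13), and against CW14 2 of 10 (13, highest other 13).

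The differences between the combined group and OTA followed GC content (rho = 0.450). Combined replicate 3 alone is argued against, since without it the rank correlation was 0.250, though that is well under the value with it. Fewer fragments in the combined libraries are argued against too, since rho was 0.498 among the 1625 genes with a mean of at least 50 FPKM. A trend on GC content and length as the whole source of the calls is argued against by the 1359 of 1960 called genes (69.3%) that kept call and direction once it was removed. A difference in library preparation between these groups, for which the labels give no batch, and an effect of the treatment itself both stay open and were not tested.

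Of the 26 NF-kB genes, 13 rose with CW14 alone and 8 had a negative interaction. The GC content and length trend is argued against, since 7 of these 8 kept it once the trend was removed. BIRC3, near the threshold (-1.93, SE 0.47, limma adjusted p = 0.0494), was not called after (-1.46, SE 0.57, adjusted p = 0.141). Combined replicate 3 alone is argued against too, since without it the 8 coefficients were -0.951 to -3.18. All 431 calls held without it, so calls kept decide nothing. If the bacteria had had no effect in the combined wells, the other genes called with CW14 should have moved either way there, and 24 of 34 (70.6%) moved in the same direction, between the bounds of 60% and 80% set beforehand, as did as many in 5 of 20 labellings of the 6 libraries, the real one included, so this stays open beside the hypothesis that OTA lowers the cytokine response to CW14. Genes called in both CW14 effects speak against such a lack of effect, 16 in the same direction and 1 opposite, FOS and HSPA6 among the former, but without control replicate 1 there were 0 and 0 and without combined replicate 3 there were 27 and 19.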

How the results depend on the processing

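The fits without small RNA genes, those with the GC content and length trend removed and the list tests that leave out 1 library were chosen after the data were seen. Of 8892 values of the 359 named results under 25 alternatives, 8075 (90.8%) kept direction and side of the threshold, 783 (8.81%) fell below it, 34 (0.382%) newly passed it and 0 reversed. Where a count moved, the cause was not tested unless given. With no filter, more genes were tested and 25 were called in CW14 against control and 235 in the interaction. With only the compared groups in the fit, 4621 were called in OTA against control, 70 in the combined group against OTA, 1596 against control and 1521 against CW14, and 32 were reversed. Array weights, by a gene-by-gene method, gave combined replicate 3 a weight of 0.0847, and 5417 genes were called in OTA against control, 195 in CW14 against control, 4425 in the combined group against OTA and 5902 against control. With them 3082 had an interaction, 8125 differed among the groups and 1798 were reversed. With the GC content and length trend removed, 734 had an interaction. Without small RNA genes, the correlation of the OTA effects was 0.578. With an estimated correlation the lists that passed were 2 in OTA against control, 3 in CW14 against control, 0 in the combined group against OTA, 1 against control, 1 against CW14 and 0 in the interaction. By fry, 4 passed in CW14 against control and 23 in the combined group against CW14.

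Leaving out 1 library gave 1299 (without OTA replicate 3) to 4364 (without combined replicate 3) calls in OTA against control and 4 (without control replicate 1) to 123 (without combined replicate 3) in CW14 against control. It gave 653 (without OTA replicate 2) to 3388 (without combined replicate 2) in the combined group against OTA, 2265 (without control replicate 1) to 4776 (without combined replicate 2) against control and 2780 (without CW14 replicate 2) to 5297 (without combined replicate 2) against CW14. For the interaction it gave 17 (without control replicate 3) to 1595 (without combined replicate 3), for any difference among the groups 3440 (without OTA replicate 3) to 6515 (without combined replicate 3) and for reversed genes 127 (without OTA replicate 3) to 1114 (without combined replicate 3). Other libraries that moved these counts by over 1.5 times are given above.

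A replicate block gave 286 genes with an interaction, 2032 called in OTA against control and 372 reversed. Of 12, 1 correlated best with a library of its own number. MT1X and MT2A peaked in replicate 1 of control and CW14, so pairing stays open.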

Other observations

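The family tests in this part and, for the immediate early genes, the tests of the GC content and length trend, of scaling and of AU-rich transcripts were chosen only after the results were seen. Genes were grouped by the prefix of their symbol into 61 families. More zinc finger genes fell than rose with OTA: of 366 tested ZNF genes 4 rose and 101 fell (camera adjusted p = 4.02e-06, 0.51 with an estimated correlation). Of 35 ZBTB genes, which encode a related class of transcription factors, 0 rose and 11 fell (camera adjusted p = 0.00149, 0.53 with an estimated correlation). Of 38 RBM genes, for RNA-binding proteins, 1 rose and 12 fell (camera adjusted p = 0.0177, 0.264 with an estimated correlation). Of 58 HIST genes, for histones, 12 rose and 1 fell with OTA (camera adjusted p = 1.76e-05, 0.359 with an estimated correlation), and 0 rose and 9 fell in the combined group against OTA (camera adjusted p = 0.000467, 0.929 with an estimated correlation). Of 50 MRPL genes, for mitochondrial ribosomal proteins, 12 rose and 1 fell in the combined group against control (camera adjusted p = 0.00562, 0.738 with an estimated correlation).

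The fall of the immediate early genes with OTA was large and broad. The GC content and length trend is argued against, since 33 of 34 members were still lower once it was removed. The scaling between libraries is argued against as well, since the list's median was -2.10 (SE 0.157) in the one of 3 other scalings nearest 0. Many immediate early transcripts are short-lived, so a hypothesis was that OTA cells lost AU-rich, short-lived transcripts in general. The 3481 other genes with as dense ATTTA motifs in the 3' untranslated region had a median log2 difference of -0.0104 (SE 0.0124). It was 0.0362 in the 7566 other genes with less dense motifs. This argues against a large fall of motif-dense genes as a whole. Motif density does not measure half-life, which was not used, so a loss of short-lived transcripts stays open. A lower activity of the kinases that switch these genes on stays open too and was not tested.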
